A study of Mus musculus with 24 samples.

How the data were processed

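Total RNA from mouse cells was measured on 24 Affymetrix whole-transcript arrays, in 6 groups of 4. The cells were of 3 kinds. C57epi.1 is an epithelial cell line from the upper reproductive tract of C57BL/6 mice. Bm12.4 is an epithelial line from the same tissue of B6(C)-H2-Ab1bm12/KhEgJ mice, a strain with a mutant MHC class II beta chain. The macrophages were grown with GM-CSF from C57BL/6 femur bone marrow. Each kind was kept in RPMI medium or given an inflammatory supernatant. Per the labels' protocols, this was conditioned medium at 33% (v/v) from a Chlamydia-specific CD4 T cell clone kept with infected epithelial monolayers, brought to 4 ng/ml interferon-gamma. RNA was column-purified with a DNase step, and 100 ng of total RNA per array was labelled with biotin.

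Per the submitters' processing notes, the arrays were handled with GCOS, Partek 6.2 and RMA, a method that corrects background, aligns the distributions of the arrays and summarises the probes of each probe set. The versions of GCOS and RMA, and the order of these steps, are not given in the sources used here. The deposited values are on the log2 scale, with 2 decimals, 1 per probe set and array. The table held 28853 probe sets and 24 columns, each matched to a sample by its label. Array medians lay between 5 and 5.19. No detection p-value per probe set was used here, so a low level cannot be told from background for a single gene. For arrays, the number of replicates, 4 per group, limits the precision.

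Gene symbols came from the platform's annotation and were checked against a RefSeq gene table of the mouse assembly GRCm38.p6. Of the probe sets, 21789 had 1 gene symbol, 1621 had several and 5443 had none. Those with several symbols or none were left out of the comparisons, and their counts of changes are given in the closing section. For 999 symbols with more than 1 probe set, the one with the highest mean over the 24 arrays was used, which set aside 1851 probe sets and left 19938 genes. No genome coordinates were used here. Some list members (among them H2-K1, H2-D1, Isg15, Irgm2, Igtp and Gbp2) had no probe set of a single symbol and were not analysed here. Families of similar sequence (Gbp, Ifi20x, Ifit, Ms4a, Trim30 and H2 genes) may share signal between members.

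All 8 comparisons used 1 model in limma 3.58.1 (R 4.3.3, statmod 1.5.0): lmFit and eBayes with defaults, a mean per group over all 24 arrays, with 18 residual degrees of freedom and 3.62 prior degrees of freedom. The comparisons were the treatment effect in each of the 3 kinds of cell, the mean of both lines against macrophages in media and in supernatant, C57epi.1 against Bm12.4 in media, and 2 interaction tests. The interactions compared the treatment effect of both lines (their mean) with that of macrophages, and that of C57epi.1 with that of Bm12.4. P-values were two-sided and adjusted by Benjamini-Hochberg over 19938 genes. A gene was called at an adjusted p under 0.05, and calls of at least 2-fold were counted beside. Differences and their standard errors (SE) are on the log2 scale, and levels are means of 4 arrays with their standard deviation (SD). The shared residual lets a group of high spread widen the error of the others.

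There were 23 gene lists, written from general knowledge of interferon and inflammatory responses, of the cells used and of other cells a culture could hold. Below, T cell costimulation genes is short for a list of T cell costimulation, inhibition and adhesion genes, Cd274 and Icam1 among them. GTPase genes is short for a list of interferon-inducible GTPases and effectors. That list also holds effectors such as Nos2, Acod1 and Slfn genes. Each was tested in each comparison with camera (preset correlation between genes 0.01, at least 5 measured members, Benjamini-Hochberg over the lists of a comparison). Members called over all genes were counted, and beside them those called when adjusted over the list alone. The tests were repeated with a correlation estimated from the data and with fry, whose p tests whether the members of a list move, on balance, in 1 direction, without comparing them with other genes.

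Genes were named by a rule. For treatment effects, it took the 6 largest rises and 4 largest falls among called genes whose 4 treated arrays all lay to 1 side of the 4 media arrays. For the other comparisons, it took the 5 largest called changes each way, for levels with arrays that did not overlap. It took 2 to 4 of the largest called members of each list described. Always named were Irf1, Ciita, H2-Ab1, Cd74, Tap1, Cd274, Cd40, Cd80, Cd86, Icam1, Nos2, Ido1, Cxcl9, Cxcl10, Il6 and Tnf, and, as checks of cell type, Epcam, Krt8, Krt18, Cdh1, Ptprc, Csf1r, Itgam, Cd68 and Vim. A further gene of that rule is not reported here. Predicted, Riken, LOC, histone, olfactory and vomeronasal receptor genes were passed over unless on a list. The model, thresholds, gene lists, naming rule and alternative settings were chosen before the data were examined.

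Whether equal replicate numbers pair arrays of different groups was checked by correlating, across genes, each array's deviation from its group mean. Equal numbers correlated at more than 0.1 in all 4 replicates for Bm12.4 media with Bm12.4 supernatant (0.23 to 0.68) and for the media arrays of both lines (0.51 to 0.63), and not for the other 13 pairs of groups. In both cases the equal number was the best match for 2 of 4 arrays. The unpaired model was therefore kept, with the replicate number as a block among the alternatives.

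The alternative settings chosen then were: only the arrays of the groups compared, a replicate block, eBayes with trend and robust options, a filter on dim genes (mean above 5.11, the median of all values, in at least 1 group), array medians aligned, quantile normalization, every probe set tested, the mean of the probe sets of a gene, an adjusted p under 0.01, an estimated correlation and fry for the lists, and leaving out each array in turn. After replicates 1 and 2 were seen to stand apart from 3 and 4, 4 more were added: replicates 1 and 2 alone, replicates 3 and 4 alone, a term for these sets (A and B) within each kind of cell, and a replicate block within the groups compared.

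The model was tested on simulated data with each gene's mean variance within groups, 200 changed genes among 19938 and 1 list shifted by 0.5. Changes of 1 on the log2 scale were recovered in 80.6% to 98.5% of cases, and changes of 0.5 in 23.9% to 68.7%. Unchanged genes made up 3.97% to 7.51% of the calls. The shifted list was called in all 8 comparisons, with 0 of the other lists. The simulated values were drawn independently for each gene and array, with equal spread in all groups and no sets A and B. Real arrays differ in this, so these rates need not hold for them. Figures were drawn with matplotlib.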

Results

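Gene expression was measured on 24 arrays from 2 mouse reproductive tract epithelial lines, C57epi.1 and Bm12.4, and from bone marrow macrophages. Each was kept in media or in an inflammatory supernatant made to mimic the milieu of a Chlamydia infection of the genital tract, with 4 arrays per group. The tables gave 19938 genes, with array medians from 5 to 5.19 on the log2 scale. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these arrays, part of which could be technical.

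The 3 kinds of cell lay far apart and the supernatant moved each of them less. The first principal component, with 66.2% of the variance, parted macrophages from both lines, and the second, with 15.7%, parted the lines. Within groups, arrays correlated across genes at 0.967 to 0.9975, and no 2 arrays held identical values. In media, replicates 1 and 2 of each line (set A) stood apart from replicates 3 and 4 (set B). Between these sets limma called 4553 genes in C57epi.1 and 5984 in Bm12.4 in media, 8 in macrophages in media, 872 in treated Bm12.4 and 336 in treated macrophages. In treated C57epi.1 it called 0, with 1303 at an unadjusted p under 0.05. Cell cycle genes were lower in replicates 3 and 4 of the media arrays, with a median difference of −1.09 in C57epi.1 and −2.38 in Bm12.4. The type I interferon genes were higher there, with medians of 0.43 and 1.26. Also called in both lines were interferon signalling (0.42 and 0.487), stromal (0.385 and 0.36), pattern recognition (0.17 and 0.282) and sterol synthesis genes (−0.332 and −0.407). Called in 1 line were matrix remodelling in C57epi.1 (0.325) and GTPase (0.47) and MHC class I genes (0.59) in Bm12.4. For comparisons that use these arrays, medians within sets A and B are therefore given where such a list was called. In treated Bm12.4 the sets parted in cell cycle (−0.675), MHC class II (0.272) and type I interferon genes (0.185). In treated C57epi.1 they parted in cell cycle (−0.19) and matrix remodelling genes (0.075). Treated macrophages had splits too, of NF-kappaB targets (−0.383, adjusted p = 9.33e-12), cell cycle (0.275), type I interferon (0.238), matrix remodelling (−0.19), pattern recognition (0.178), cytokine (−0.17), female tract (−0.115) and macrophage marker genes (0.08). In media the macrophage sets parted in cell cycle (0.43), MHC class II (0.193) and sterol synthesis genes (−0.15). Of the lists named for treated C57epi.1 and for macrophages in media, limma called 0 members. The sets were defined after the split was seen. No repeat of these list tests between sets with an estimated correlation is given here, so their calls lack that check.

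**Figure D1:**
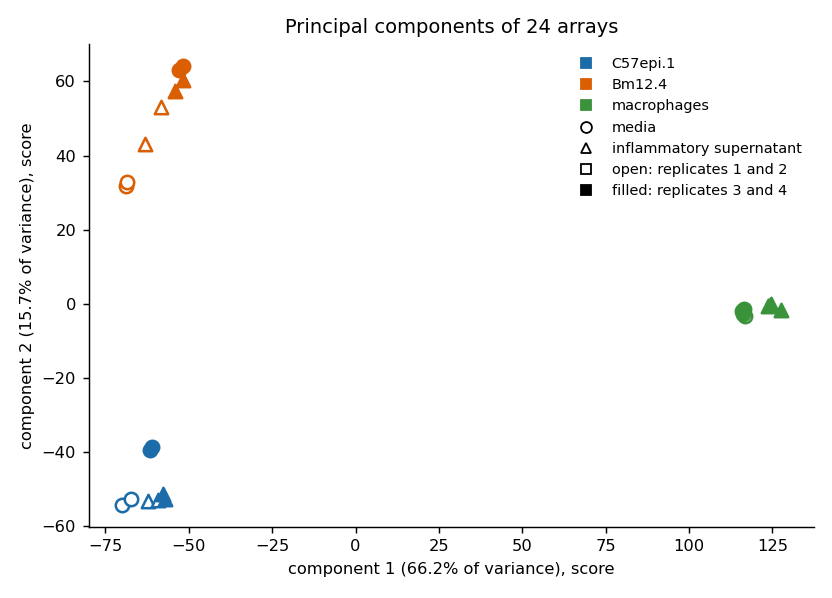
Scores of the 24 arrays on the first (66.2% of the variance) and second (15.7%) principal components, with 1 point per array, colour for the kind of cell and shape for the treatment. Open points are replicates 1 and 2 and filled points replicates 3 and 4, which lie apart in the media arrays of both lines.

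The first question was how reproductive tract epithelial cells and macrophages differ at baseline. In media, the macrophages carried the genes of phagocytes and antigen-presenting cells. These include the oxidase subunit Cybb, the scavenger receptor Cd36, the lectin Clec4n, the protease Ctss and the MHC class II genes H2-Aa, H2-Ab1 and Cd74. As a list, dendritic cell markers such as Clec9a were higher in the macrophage cultures too. Whether these cultures held dendritic cells was not tested. The lines carried the simple-epithelium keratin Krt19, the transcription factor Nfib, the membrane protein Tm4sf1, the chemokine Cxcl12 and the collagen-processing factor Pcolce. They also held high levels of stromal genes such as Sparc, Col3a1 and Dcn, while the epithelial adhesion genes Epcam and Cdh1 were low.

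Cybb (probe set 10603551) had a log2 level of 3.48 ± 0.09 (SD, n = 4) in C57epi.1, 3.73 ± 0.14 in Bm12.4 and 13.57 ± 0.02 in macrophages, a difference of −9.96 (SE 0.07, adjusted p = 1.19e-29). Next came Mmp12 at −9.91, Clec4n at −9.83, Cd36 at −9.66 and Ctss at −9.51. In the other direction were Nfib at 7.44 (SE 0.117, adjusted p = 1.07e-23), Krt19 at 7.22, Tm4sf1 at 6.98, Cxcl12 at 6.79 and Pcolce at 6.72. Of the checks of cell type, Ptprc (−7.17), Csf1r (−7.53), Itgam (−8.6) and Cd68 (−6.4) were far lower in the lines and Vim slightly lower (−0.53). Krt8 was higher in the lines (2.08, adjusted p = 4.75e-11), Cdh1 was lower (−2.23, adjusted p = 8.73e-08), and neither Epcam (0.01, adjusted p = 0.945) nor Krt18 (−0.1, adjusted p = 0.566) was called. Krt8 rested on C57epi.1, at 9.25 ± 0.4, against 5.67 ± 0.21 in Bm12.4 and 5.38 ± 0.41 in macrophages.

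**Figure D2:**
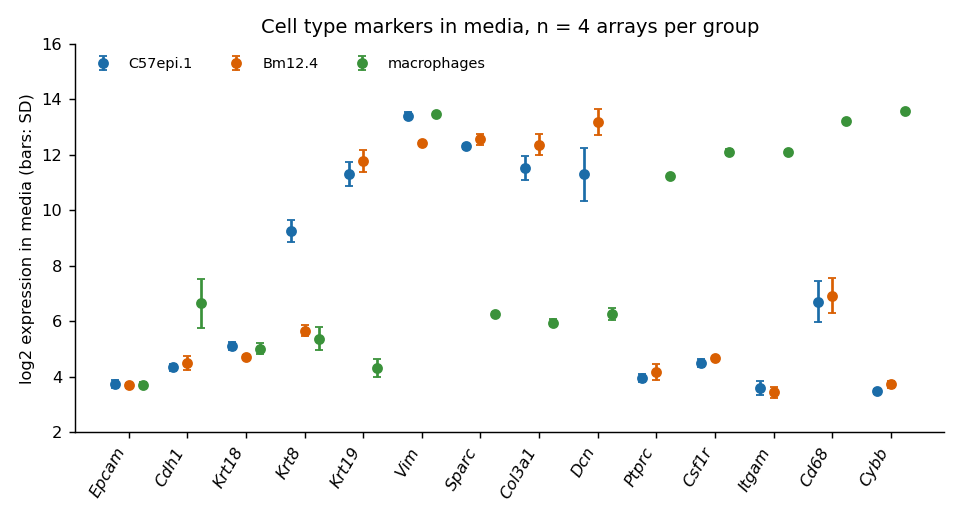
Log2 levels of marker genes in media, means of 4 arrays per group with bars for the SD, for both lines and macrophages. Cybb lies at 13.57 in macrophages and at 3.48 in C57epi.1, and Epcam near 3.7 in all 3.

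Macrophage markers were lower in the lines for 38 of 39 genes, with Cybb, Clec4n and Lyz2 (−9.47) furthest (median −6.87, adjusted p = 1.47e-40). Genes of alternative activation, the wound-healing state of macrophages, were lower for 17 and higher for 1 of 19 (median −4.02), led by Cd36, Chil3 (−8.57) and Arg1 (−8). MHC class II genes were lower for 13 and higher for 1 of 16 (−2.65), with H2-Aa at −8.64, H2-Ab1 at −8.25 and Cd74 at −7.15. MHC class I genes were lower for 17 of 21 (−1.33, or −1.22 and −1.17 in sets A and B), among them Psmb8 (−4.54) and H2-Q4 (−4.32). Pattern recognition genes were lower for 26 and higher for 1 of 34 (medians −1.49 and −1.43 in sets A and B), led by Clec7a (−8.15) and Tlr13 (−7.05). T cell costimulation genes were lower for 23 and higher for 6 of 33, with Slamf7 at −7.14 and Cd274 at −6.73 against Vcam1 at 6.02. Dendritic cell markers, led by Clec9a (−4.8), were lower for 8 of 15, and adjusted over the list alone 1 was higher. These 7 lists were also called with an estimated correlation, and 11 others were not. Of those, stromal genes were higher for 19 and lower for 6 of 29 (adjusted p = 5.21e-06, and adjusted p = 0.159 with an estimated correlation), with Sparc at 6.17, Col3a1 at 5.99 and Dcn at 5.98 and medians of 1.86 and 2.22 in sets A and B. Cell cycle genes were higher for 28 of 33 (adjusted p = 1.21e-05, and adjusted p = 0.385 with an estimated correlation), led by Cdc20 (3.05). Their median was 3.14 in replicates 1 and 2 and 0.822 in replicates 3 and 4. Sterol synthesis genes (13 higher, 3 lower of 20, Cyp51 at 2.18, medians 0.63 and 0.515 in sets A and B) and female tract genes (7 higher, 2 lower of 20, Hoxa9 at 2.37 and Emx2 at 2.04) were higher with adjusted p = 0.0107 and 0.0421, and adjusted p = 0.385 and 0.326 with an estimated correlation. The lower lists in that position were the interferon-inducible GTPases (13 lower, 1 higher of 19, Slfn5 −5.12, adjusted p = 9.1e-05, medians −1.06 and −1.28 in sets A and B), interferon signalling (15 and 3 of 24, Irf8 −4.56, adjusted p = 0.000443, medians −1.23 and −0.715), type I interferon (18 and 6 of 34, adjusted p = 0.0397, medians −1.25 and −0.236 in sets A and B), cytokines (16 and 5 of 40, Il1a −5.17, adjusted p = 0.0144), NF-kappaB targets (16 and 7 of 30, Cfb −5.48, adjusted p = 0.0209), neutrophil markers (10 of 20, Mmp8 −7.88, adjusted p = 0.00756) and endothelial markers (4 and 1 of 11, Vwf −4.78, adjusted p = 0.0314). With an estimated correlation these had adjusted p = 0.119, 0.326, 0.637, 0.143, 0.326, 0.119 and 0.217. Over all alternatives the adjusted p of these 11 lists ran from 8.25e-16 to 0.637. Female tract genes lost the call without C57epi.1 replicate 2, Bm12.4 replicate 3 or 4 or macrophage replicate 1 (adjusted p = 0.0525, 0.0624, 0.0565 and 0.0507). So did type I interferon genes without C57epi.1 replicate 2, Bm12.4 replicate 1 or 2 or macrophage replicate 2 or 3 (adjusted p = 0.0611, 0.0539, 0.066, 0.0634 and 0.051).

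In all, 9393 genes differed, 4929 higher and 4464 lower in the lines, and 3992 by at least 2-fold. Tested in each set alone, 6953 genes were called in both with the same direction and 250 with opposite ones. Epithelial markers as a list were not called (11 higher, 7 lower of 41, adjusted p = 0.436). Krt19 and Krt14 (4.72) were higher in the lines, and Spint1 (−4.93) and Itga6 (−4.46) were lower.

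The lines differed from each other in 4873 genes in media. C57epi.1 carried more of the myosin Myh10, the pantetheinase Vnn1, the collagen gene Col1a2, its crosslinking enzyme Lox and the growth factor Fgf7. Bm12.4 carried more Pkhd1l1, Tmem45a, the carbonic anhydrase Car13, the vessel ligand Angpt1 and Capn6. Many type I interferon genes and the acute phase gene Saa3 were higher in Bm12.4. As a list, the interferon genes were not called with an estimated correlation (adjusted p = 0.5), and the size of their difference moved with the set. The keratins Krt8 and Krt14 and the cadherin Cdh3 were higher in C57epi.1.

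Myh10 (probe set 10377319) stood at 11.81 ± 0.37 (SD, n = 4) in C57epi.1 and 4.7 ± 0.16 in Bm12.4, a difference of 7.11 (SE 0.151, adjusted p = 5.59e-20), and Pkhd1l1 at 3.98 ± 0.16 and 11.61 ± 0.55 (−7.63, SE 0.168, adjusted p = 8.94e-20). Vnn1 (7.02), Col1a2 (6.42), Lox (6.33) and Fgf7 (6.22) followed on the C57epi.1 side. Tmem45a (−7.31), Car13 (−7.1), Angpt1 (−7.03) and Capn6 (−6.91) followed on the other. Krt8 differed by 3.58 (11.9-fold, adjusted p = 1.92e-13) and Krt18 by 0.37 (adjusted p = 0.0808). Krt18 was called when the model held only the arrays of these 2 groups (adjusted p = 0.0345, with 0.033 to 0.269 over all alternatives). None of the 5 lists that follow was called with an estimated correlation in limma's camera, where adjusted p = 0.5, 0.5, 0.695, 0.811 and 0.943 in the order given and 0 lists had an unadjusted p under 0.05. With fry 11 lists were called. With the preset correlation, type I interferon genes were lower in C57epi.1 for 28 and higher for 1 of 34 (median −1.31, adjusted p = 3.47e-11), or 29 and 1 adjusted over the list alone, with Parp12 at −4.3, Phf11d at −3.63 and Ifit1 at −3.45. Their median was −0.695 in replicates 1 and 2 and −1.87 in replicates 3 and 4, so the size moved with the set. Interferon-inducible GTPase and effector genes were lower for 8 of 19 (Slfn2 −3.24, Gbp3 −2.43, adjusted p = 0.0105, medians −0.27 and −0.745 in sets A and B). MHC class I genes were lower for 8 of 21 (Tap1 −3.39, adjusted p = 0.0404, medians −0.09 and −0.425). Sterol synthesis genes were higher for 9 and lower for 1 of 20 (Idi1 1.61, Fdps 1.23, adjusted p = 0.0105, medians 0.423 and 0.467). Cell cycle genes were higher for 3 of 33 (Cdc20 1.68, adjusted p = 0.0404), with a median of 1.44 in replicates 3 and 4, where 24 were called, against 1 called each way in replicates 1 and 2. Over all alternatives the adjusted p of these 5 lists ran from 1.16e-21 to 0.964. MHC class I genes lost the call without C57epi.1 replicate 2 or Bm12.4 replicate 3 or 4 (adjusted p = 0.082, 0.121 and 0.0855), and sterol synthesis genes without C57epi.1 replicate 2 or Bm12.4 replicate 4 (adjusted p = 0.082 and 0.0855). Cell cycle genes lost it without C57epi.1 replicate 1 or 2 or Bm12.4 replicate 3 or 4 (adjusted p = 0.203, 0.201, 0.654 and 0.444).

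Of 4873 genes called, 2383 were higher in C57epi.1 and 2490 lower, 1503 by at least 2-fold. Among lists that were not called, epithelial markers were higher for 8 and lower for 2 of 41 (Cdh3 4.72, Krt14 3.17), stromal genes 6 and 7 of 29 (Col1a2 6.42, Fbln1 −5.88, Eng −4.38) and female tract genes 3 and 4 of 20 (Hoxa11 2.99, Esr1 −1.78).

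The next question was how each kind of cell responds to the supernatant. In C57epi.1, the supernatant raised the classical interferon programme. The largest rises were in the guanylate-binding protein Gbp3, the immunity-related GTPase Iigp1, Trim30a, Ifit3, the DNA sensor family member Ifi205 and the T cell chemokine Cxcl9. MHC class II genes, with their master regulator Ciita, rose in these non-phagocytic cells, as did the T cell inhibitory ligand Cd274 (PD-L1), the nitric oxide synthase Nos2 and the cytokine Il6. The largest falls were in the matrix proteoglycans Fmod and Prelp, the calcium-binding S100a4 and Kazald1.

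Iigp1 (probe set 10455961) rose by 7.53 (SE 0.454, adjusted p = 2.34e-11), from 3.52 ± 0.32 to 11.05 ± 0.05 (SD, n = 4). A level as low as 3.52 cannot be told from background here, so the size and rank of rises from such levels hold for the array values alone. Gbp3 rose by 7.78, Trim30a by 7.35, Ifit3 by 7.33, Ifi205 by 7.13 and Cxcl9 by 7.11. Fmod fell by 2.75 (SE 0.497, adjusted p = 0.000308), and S100a4 (−2.53), Prelp (−2.48) and Kazald1 (−2.41) fell too. Cd74 rose by 5.09, from 4.39 ± 0.39 to 9.48 ± 0.21, H2-Ab1 by 3.03 and Ciita by 2.39. Irf1 (3.55), Tap1 (2.33), Cd274 (4.84), Icam1 (0.87), Nos2 (4.91), Ido1 (1.56), Cxcl10 (6.48) and Il6 (2.09) rose, each with all 4 treated arrays above all 4 media arrays. Cd40 was called lower by a small amount (−0.32, adjusted p = 0.0396, 3 of 4 treated arrays below all media arrays). It was not called without media replicate 2, 3 or 4 (adjusted p = 0.104, 0.0631 and 0.129) or treated replicate 1, 2 or 4 (adjusted p = 0.0642, 0.143 and 0.0713). Cd80 (0.27, adjusted p = 0.25), Cd86 (−0.07, adjusted p = 0.759) and Tnf (0.13, adjusted p = 0.765) were not called.

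Among the lists, 19 of 19 interferon-inducible GTPase and effector genes rose (median 5.42, adjusted p = 3.39e-47), and 31 of 34 type I interferon genes (4.74, adjusted p = 1.11e-60), with Mx2 at 7.01 and Usp18 at 6.57. Their medians in sets A and B were 5.62 and 5.49 for the GTPase list and 4.91 and 4.44 for type I interferon. MHC class I genes rose for 14 and fell for 1 of 21, or 16 and 2 adjusted over the list alone (H2-T24 3.96, Psmb10 3.1, Psmb8 3.09, medians 1.57 and 1.27 in sets A and B). Of the MHC class II list, 7 of 16 rose and 1 fell (H2-Aa 5.28, Ctss 3.46). Chemokines rose for 8 and fell for 1 of 33 (Cxcl11 4.88, Ccl7 3.88), and cytokines 10 and 3 of 40 (Il15 3.15, Il18bp 2.85). Genes of T cell costimulation, inhibition and adhesion rose for 10 and fell for 1 of 33 (Cd274 4.84, Lgals9 1.9, Pvr 1.42). Cd40, Cd80 and Cd86 were not called higher. NF-kappaB targets rose for 18 and fell for 1 of 30 (Cfb 5.37, Saa3 2.93, Ptgs2 2.52), and cell death genes 9 and 2 of 22 (Tnfsf10 4.5, Daxx 2.51). These 9 lists were also called with an estimated correlation. Interferon signalling genes (11 rose, 4 fell of 24, Irf7 5.4, Batf2 4.73, Stat2 3.39, medians 0.738 and 0.105 in sets A and B) had adjusted p = 2.58e-06, and adjusted p = 0.216 with an estimated correlation. Pattern recognition genes (11 rose, 1 fell of 34, Tlr3 3.83, Casp4 2.86, medians 0.168 and −0.0375 in sets A and B) had adjusted p = 7.46e-05, and adjusted p = 0.147 with an estimated correlation. Stromal genes fell for 10 and rose for 1 of 29 (Pdgfra −2.18, Snai1 −1.71, medians −0.175 and −0.37 in sets A and B, adjusted p = 0.0011, and adjusted p = 0.372 with an estimated correlation). Sterol synthesis genes fell for 4 of 20 (Hmgcs1 −0.85, Insig1 −0.84, medians −0.435 and −0.0825 in sets A and B, adjusted p = 0.0202, and adjusted p = 0.586 with an estimated correlation). That list lost the call without media replicate 1 or 2 or treated replicate 1 (adjusted p = 0.0784, 0.232 and 0.0596). Over all alternatives the adjusted p of these 4 lists ran from 1.17e-10 to 0.916.

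The lists not called in C57epi.1 were matrix remodelling (3 rose, 4 fell of 25, Mmp13 1.91, Mmp2 −1.22), alternative activation (1 and 1 of 19, Tgm2 1.59), epithelial markers (4 and 2 of 41, Krt7 −0.69, Krt18 0.52), female tract genes (1 and 3 of 20, Hoxa10 −0.61), dendritic cell markers (1 of 15 rose) and T, NK and B cell markers (1 of 20 rose). Macrophage markers (2 rose, 3 fell of 39) were not called either, though Mpeg1, a pore-forming protein of phagocytes, rose by 6.57. Mmp2 was not called without media replicate 4 (adjusted p = 0.0532), nor Krt18 without media replicate 3 or 4 or treated replicate 1 (adjusted p = 0.0502, 0.0505 and 0.0627). Neutrophil markers and endothelial markers had 0 of 20 and 0 of 11 members called by limma, with 2 and 0 at an unadjusted p under 0.05. Cell cycle genes had 0 of 33, with 1 unadjusted (median 0.04). Their median was −0.42 in replicates 1 and 2 and 0.54 in replicates 3 and 4, so it changed sign with the set. In all, 3832 genes were called, 1765 up and 2067 down, and 509 rose and 256 fell by at least 2-fold. The share that rose was 46.1%, 53.1% with array medians aligned and 44.7% with quantile normalization. Tested in each set alone, 1673 genes were called in both with the same direction and 37 with opposite ones.

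**Figure D3:**
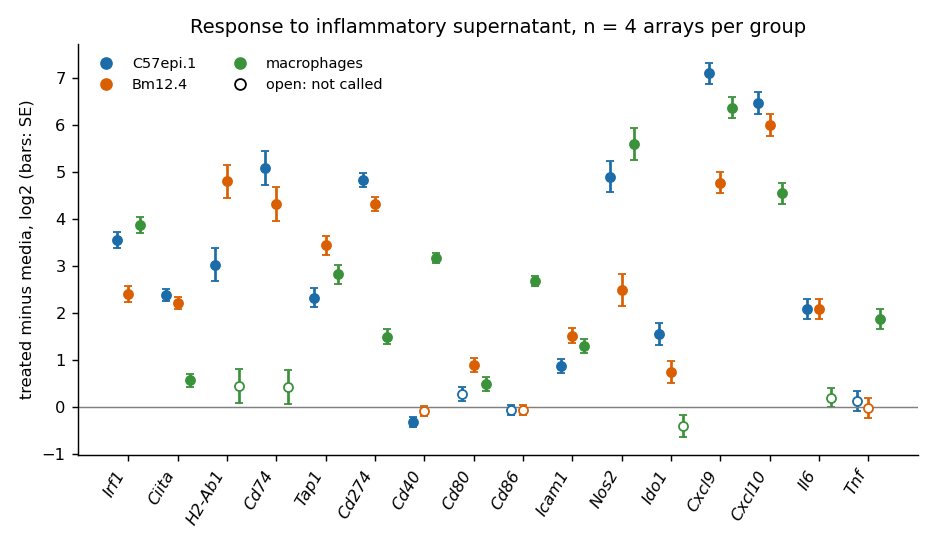
Treated minus media, log2, for the genes named in every treatment effect, with bars for the SE and 4 arrays per group in C57epi.1, Bm12.4 and macrophages. Open points were not called, among them Cd86 in both lines (−0.07) and Cd74 in macrophages (0.42).

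Bm12.4 also mounted an interferon response. Its largest rises were in Gbp4, Ifi205, the surface protein Ly6e, Trim30a, Iigp1 and Gm4951, a GTPase of the Iigp1 family. Cd274, the chemokines Cxcl9 and Cxcl10, Il6 and MHC class II genes rose too. Of 539 falls, 24 reached 2-fold, the largest in the neuronal leucine-rich protein Lrrn3, the carboxylase subunit Pccb, Fmo4 and the growth factor-binding Igfbp5.

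Ly6e (probe set 10424676) rose by 6.73 (SE 0.16, adjusted p = 3.11e-18), Gbp4 by 7.1, Ifi205 by 6.84, Trim30a by 6.43, Iigp1 by 6.4 and Gm4951 by 6.32. Iigp1 was spread in media (5.42 ± 1.67, SD, n = 4) and not after treatment (11.81 ± 0.1). Lrrn3 fell by 1.92 (SE 0.142, adjusted p = 1.01e-09), and Pccb (−1.74), Fmo4 (−1.65) and Igfbp5 (−1.64) fell too. Fmo4 was not called without media replicate 3 or 4 or treated replicate 1 or 4 (adjusted p = 0.0711, 0.0605, 0.0938 and 0.0608). H2-Ab1 rose by 4.81, from 4.17 ± 0.1 to 8.98 ± 1.27, Cd74 by 4.32 and Ciita by 2.22. Irf1 (2.41), Tap1 (3.45), Cd274 (4.33), Cd80 (0.89), Icam1 (1.52), Nos2 (2.5), Cxcl9 (4.78), Cxcl10 (6) and Il6 (2.09) rose with all treated arrays above all media arrays. Ido1 rose at the edge of the threshold (0.75, adjusted p = 0.0493), and treated replicate 1 lay apart, at 4.99 against a mean of 4.06 in the others. Leaving out any 1 of the 8 arrays ended that call (adjusted p = 0.0808, 0.106, 0.0803 and 0.0701 without media replicates 1 to 4 in turn, and 0.2, 0.0536, 0.0541 and 0.058 without treated replicates 1 to 4). Cd40 (−0.09, adjusted p = 0.757), Cd86 (−0.07, adjusted p = 0.825) and Tnf (−0.02, adjusted p = 0.978) were not called.

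The GTPase list rose for 17 of 19 genes (median 5.04, adjusted p = 2.22e-54), and type I interferon genes rose for 33 of 34 (3.56, adjusted p = 3.13e-89), led after Trim30a by Rsad2 (5.86), Ifit3 (5.5) and Cmpk2 (5.35). Their medians in sets A and B were 5.28 and 3.78 for the GTPase list and 4.44 and 2.71 for type I interferon. Interferon signalling genes rose for 11 of 24 (Batf2 4.87, Irf7 4.05, medians 0.588 and 0.225 in sets A and B). MHC class I genes rose for 15 and fell for 1 of 21, or 16 and 2 adjusted over the list alone (H2-Q4 5.2, Psmb9 4.44, medians 1.55 and 0.98 in sets A and B), and MHC class II genes rose for 7 and fell for 2 of 16 (H2-Aa 5.46, H2-Eb1 3.48). In the treated arrays the MHC class II list was higher in set B than in set A, by a median of 0.272. Chemokines rose for 9 of 33 (Ccl2 2.94, Ccl7 2.56), NF-kappaB targets for 21 of 30 (Cfb 5.44, Lcn2 2.79), pattern recognition genes for 16 of 34 (Ifih1 2.96, Tlr3 2.78, medians 0.367 and 0.555 in sets A and B) and cell death genes for 9 of 22 (Tnfsf10 4.83, Daxx 2.69). Genes of T cell costimulation, inhibition and adhesion rose for 8 and fell for 1 of 33 (Cd274 4.33, Lgals9 1.68, Icam1 1.52), with a median of −0.005 but a mean of 0.342. These 10 lists were also called with an estimated correlation. Cytokines rose for 6 of 40, or 8 adjusted over the list alone (Il15 3.84, Il18bp 2.86, Csf1 0.89), with a median of −0.005 and a mean of 0.249 (adjusted p = 0.0133, and adjusted p = 0.116 with an estimated correlation). The cell cycle list was called up (median 0.412, adjusted p = 0.00347, and adjusted p = 0.704 with an estimated correlation), though limma called 0 of its 33 genes, 0 also at an unadjusted p under 0.05. Its median was −0.38 in replicates 1 and 2 and 1.22 in replicates 3 and 4, where 30 genes rose. The list lost the call without media replicate 3 or 4 or treated replicate 1 (median 0.0158, 0.0983 and 0.271, adjusted p = 0.813, 0.48 and 0.115), and had a median of 0.78 and 0.827 without media replicates 1 and 2. Over all alternatives the adjusted p of the cytokine and cell cycle lists ran from 4.98e-25 to 0.813.

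Not called were matrix remodelling (3 of 25 rose, Mmp13 1.73, Tnc 1.12, adjusted p = 0.0656), sterol synthesis (Hmgcs1 fell by 0.73), alternative activation (1 of 19 rose, Slc7a2 1.21), macrophage markers (3 of 39 rose, Mpeg1 by 6.25), dendritic cell markers (1 of 15 rose, Ly75 1.23), neutrophil markers (1 of 20 rose, Mmp8 1.12) and stromal genes (2 rose, 1 fell of 29, Zeb2 0.94, S100a4 −0.71). In the epithelial, female tract, lymphocyte and endothelial lists limma called 0 members, with 4, 2, 0 and 1 at an unadjusted p under 0.05. Tnc was not called without media replicate 3 or treated replicate 1 or 2 (adjusted p = 0.0606, 0.0517 and 0.062), nor S100a4 without media replicate 2 or 4 or treated replicate 3 (adjusted p = 0.0555, 0.0802 and 0.12). Mmp8 rose by 0.73 without media replicate 1. Matrix remodelling was called without media replicate 3 or 4 (adjusted p = 0.0249 and 0.0274) and sterol synthesis without media replicate 4 (adjusted p = 0.00917). In all, 1445 genes were called, 906 up and 539 down, and 346 rose and 24 fell by at least 2-fold. The share that rose was 62.7%, 72.8% with array medians aligned and 52.9% with quantile normalization. Called in each set alone were 753 genes with the same direction and 83 with opposite ones, and the changes in the sets correlated across genes at 0.608. Of the 35 ways to split these 8 arrays 4 against 4, a pair of others called as many genes, up to 3789 for the split into sets A and B, so that share does not exclude chance.

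Macrophages shared the interferon response. Iigp1, Gm4951, the membrane protein Ms4a4c, Gbp4, Cxcl9 and Ifit2 rose most. The costimulatory genes Cd40 and Cd86 and the cytokine Tnf rose, none of which was called higher in either line, and the interleukin-12 subunit Il12b rose too. H2-Ab1 and Cd74, already high in media, rose by 0.45 and 0.42 and were called only when the model held the macrophage arrays alone. Other MHC class II genes, such as H2-Oa (1.83), were called. The largest falls were in Mamdc2, the amino acid transporter Slc36a2, Bex1 and Igfbp4. Falls were called for 9 of 33 cell cycle and 9 of 20 sterol synthesis genes, though neither list was called with an estimated correlation (adjusted p = 0.575 and 0.149).

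Iigp1 rose by 7.58 (SE 0.454, adjusted p = 2.55e-11), Gm4951 by 6.69, Ms4a4c by 6.42, Gbp4 by 6.42, Cxcl9 by 6.38 and Ifit2 by 6.32. Mamdc2 fell by 4.25 (SE 0.196, adjusted p = 2.22e-13), and Slc36a2 (−3.98), Bex1 (−3.63) and Igfbp4 (−2.69) fell too. Cd40 rose by 3.17, from 5.42 ± 0.11 to 8.59 ± 0.2 (SD, n = 4), Cd86 by 2.68, from 7.65 ± 0.17 to 10.33 ± 0.19, and Tnf by 1.88. Irf1 (3.87), Ciita (0.57), Tap1 (2.83), Cd274 (1.5), Cd80 (0.49, adjusted p = 0.0299), Icam1 (1.3), Nos2 (5.6) and Cxcl10 (4.55) rose with all treated arrays above all media arrays. Cd80 was not called without media replicate 1, 2 or 3 (adjusted p = 0.0726, 0.0654 and 0.0693) or any treated replicate from 1 to 4 (adjusted p = 0.0655, 0.0613, 0.0603 and 0.0581). Il6 (0.2, adjusted p = 0.705) and Ido1 (−0.4, adjusted p = 0.349) were not called. Neither were H2-Ab1 (0.45, adjusted p = 0.549) and Cd74 (0.42, adjusted p = 0.606), though 4 and 3 of 4 treated arrays lay above all media arrays. With only the macrophage arrays in the model both were called (adjusted p = 0.0289 and 0.0276), while over all alternatives adjusted p ran from 0.0289 to 0.736 and from 0.0276 to 0.744.

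GTPase genes rose for 17 of 19 (median 4.27, adjusted p = 1.69e-42) and type I interferon genes for 33 of 34 (3.06, adjusted p = 4.42e-60), with Ifit3 at 6.16 and Ifit1 at 5.51 and medians of 3.06 and 3.17 in sets A and B. Interferon signalling genes rose for 13 and fell for 1 of 24, or 17 and 1 adjusted over the list alone (Irf7 5.39, Batf2 3.45), and MHC class I genes rose for 17 of 21 (H2-Q4 2.96, H2-T24 2.95). Chemokines rose for 11 and fell for 3 of 33 (Ccl2 4.35, Ccl5 3.79), cytokines 11 and 1 of 40 (Il1f9 3.58, Il33 3.29, Il12b 2.11, medians 0.217 and 0.11 in sets A and B), and T cell costimulation genes 17 and 4 of 33 (Tnfsf15 3.16, Tnfsf8 2.2). NF-kappaB targets rose for 18 of 30 (Ptgs2 3.12, Cfb 2.77, medians 0.788 and 0.425 in sets A and B), pattern recognition genes for 19 of 34 (Ddx58 2.73, Nod1 2.5, medians 0.483 and 0.638) and cell death genes for 12, with 1 lower, of 22 (Tnfsf10 4.31, Mlkl 2.29). These 10 lists were also called with an estimated correlation. MHC class II genes rose for 4 and fell for 1 of 16 (H2-Oa 1.83, Ctsl −0.6, medians 0.535 and 0.122 in sets A and B, adjusted p = 0.0155, and adjusted p = 0.365 with an estimated correlation). Sterol synthesis genes fell for 9 of 20, or 13 with 1 higher adjusted over the list alone (Stard4 −1.04, Hmgcs1 −1, medians −0.62 and −0.475 in sets A and B, adjusted p = 7.53e-07, and adjusted p = 0.149 with an estimated correlation). Cell cycle genes fell for 9 and rose for 1 of 33 (Ccna2 −2.5, Ccnb2 −2.06, adjusted p = 0.000294, and adjusted p = 0.575 with an estimated correlation), with medians of −0.7 and −0.86 in sets A and B. Stromal genes fell for 6 and rose for 2 of 29 (S100a4 −2.41, adjusted p = 0.0172, and adjusted p = 0.505 with an estimated correlation). Over all alternatives the adjusted p of these 4 lists ran from 3.54e-11 to 0.575.

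Lists not called in macrophages were alternative activation (6 rose, 4 fell of 19, Pdcd1lg2 1.84, Mrc1 −2.05), matrix remodelling (4 and 4 of 25, Plau 1.39, Timp2 −1.53), macrophage markers (7 and 8 of 39, Siglec1 2.8, Fcgr1 2.06), dendritic cell markers (2 and 3 of 15, Ccr7 1.39), neutrophil markers (2 of 20 rose, Ly6g 1.55), endothelial markers (2 and 1 of 11, Vwf −1.97), epithelial markers (2 and 1 of 41, Itga6 −1.59) and lymphocyte markers (Cd28 −1.66). Neutrophil markers were called without media replicate 2 or 3 or treated replicate 2 (adjusted p = 0.0238, 0.0196 and 0.0157). Female tract genes had 0 of 20 called by limma, with 1 at an unadjusted p under 0.05. In all, 2482 genes were called, 1223 up and 1259 down, and 418 rose and 215 fell by at least 2-fold. The share that rose was 49.3%, 55.8% with array medians aligned and 47.7% with quantile normalization.

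**Figure D4:**
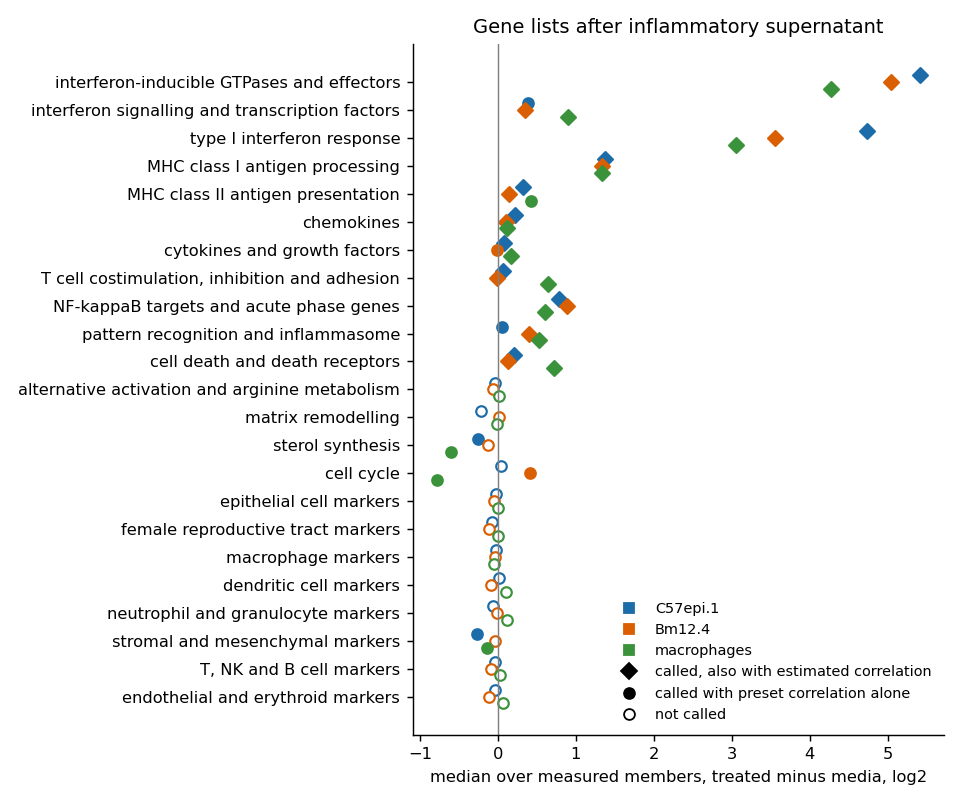
Median over the measured members of each of 23 gene lists, treated minus media on the log2 scale, by kind of cell. Diamonds were called also with an estimated correlation, filled circles with the preset correlation alone and open circles not at all. Interferon-inducible GTPase and effector genes have medians of 5.42, 5.04 and 4.27.

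The rise of the GTPase and type I interferon lists was shared, as given above. In all 3 kinds of cell, 356 genes rose and 110 fell, on those lists or not, against 4.92 and 3.53 for independent lists of these sizes. Such expected counts treat every gene, dim ones included, as equally likely to be called, so they may be too low. At 2-fold, 164 rose and 1 fell. Between the lines 572 rises and 286 falls were shared, against 80.2 and 55.9 for independent lists. C57epi.1 and macrophages shared 506 and 397, and Bm12.4 and macrophages 438 and 157. Across genes, which are not independent replicates, the treatment effects correlated at 0.719 between the lines, 0.528 between C57epi.1 and macrophages and 0.53 between Bm12.4 and macrophages.

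The response of both lines differed from that of macrophages in genes of antigen presentation and costimulation, by the interaction test of single genes. The lists of MHC class II and T cell costimulation genes were called with the preset correlation and not with an estimated one (adjusted p = 0.641 for both). The inhibitory ligand Cd274 and MHC class II genes (H2-Aa, Cd74, H2-Ab1, Ctss) rose more in the lines, from low levels in media. For Cd274 the greater rise (3.08) was smaller than the gap in media (−6.73), so the treated lines, by their mean, stayed below treated macrophages. Cd40, Cd86 and the cytokines Tnf, Il33, Il1f9 and Il12b rose more in macrophages, and Il6 rose more in the lines. Mpeg1, Ms4a4d, Apol10b and Trim30a rose more in the lines, and Ms4a4c, Ms4a6b, Ms4a6c, the vasoconstrictor Edn1 and Slfn1 more in macrophages.

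Mpeg1 (probe set 10461721) differed by 6.16 (SE 0.228, adjusted p = 3.71e-14), from 3.71 to 10.28 in C57epi.1 and from 12.75 to 13 in macrophages. H2-Aa differed by 4.94, Ms4a4d by 4.79, Apol10b by 4.76 and Trim30a by 4.58. In the other direction were Ms4a4c (−5.71, adjusted p = 4.44e-14), Ms4a6b (−5.42), Ms4a6c (−5.31), Edn1 (−4.82) and Slfn1 (−4.04). Cd74 differed by 4.28 (adjusted p = 5.96e-07), H2-Ab1 by 3.47, Cd274 by 3.08, Il6 by 1.9, Ciita by 1.73, Cxcl10 by 1.69 and Ido1 by 1.55. Cd40 differed by −3.37 (adjusted p = 4.46e-14), Cd86 by −2.75, Nos2 by −1.9, Tnf by −1.82 and Irf1 by −0.89. The differences of Nos2 and Irf1 came mainly from Bm12.4. Nos2 rose by 2.5 there, 4.91 in C57epi.1 and 5.6 in macrophages, and Irf1 by 2.41, 3.55 and 3.87. In the lists, a positive difference is a greater rise or a smaller fall in the lines. None of the 5 lists that follow was called with an estimated correlation (adjusted p = 0.641 for each, 1 list at an unadjusted p under 0.05, and 4 lists called with fry). With the preset correlation, MHC class II genes had a positive difference for 7 and a negative one for 2 of 16 (median 0.338, or 0.439 and 0.35 in sets A and B, adjusted p = 0.000549). For T cell costimulation genes these were 4 and 9 of 33 (Tnfsf15 −2.53, adjusted p = 0.0116). For type I interferon genes they were 14 and 4 of 34 (Mx2 2.49, Usp18 2.31, Cmpk2 −2.17, adjusted p = 0.000127), with medians of 1.47 and 0.292 in sets A and B. The difference of Cmpk2 came from C57epi.1 (−0.06), since it rose by 5.35 in Bm12.4 and 4.81 in macrophages. For sterol synthesis genes they were 3 and 1 of 20 (Fdps 0.75, Pmvk −0.69, adjusted p = 0.008), with medians of 0.282 and 0.501 in sets A and B. For cell cycle genes they were 6 and 1 of 33 (Ccna2 2.79, Top2a 2.26, adjusted p = 8.24e-06), with medians of 0.275 and 1.8 in sets A and B. Fdps went from 7.44 to 6.7 and Ccna2 from 7.76 to 5.26 in macrophages, against 9.06 to 9.04 and 10.62 to 10.57 in C57epi.1, so these 2 differences came mainly from falls in macrophages. Over all alternatives their adjusted p ran from 1.38e-26 to 0.641. Ccna2 and Top2a were not called without treated macrophage replicate 1 (adjusted p = 0.0504 and 0.0515). Fdps was not called without any of 13 of the 24 arrays: C57epi.1 media replicates 3 and 4 (adjusted p = 0.0542 and 0.0518) and treated replicates 2, 3 and 4 (0.0565, 0.0548 and 0.05), treated Bm12.4 replicates 1 and 2 (0.0508 and 0.0562), macrophage media replicates 1 and 2 (0.0619 and 0.103) and treated macrophage replicates 1 to 4 (0.0624, 0.078, 0.0519 and 0.0552). In all, 1611 genes differed, 852 higher and 759 lower, 523 by at least 2-fold.

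The lines also differed from each other in their response. C57epi.1 showed larger changes of the purine enzyme Xdh, the peptide Apela, Cxcl11, Phf11d and Nos2. Bm12.4 showed larger changes of the interferon-induced Cmpk2, Ly6e and Parp12, the immunoproteasome subunit Psmb9 and the MHC class I gene H2-Q4. Cmpk2, Psmb9 and Parp12 were not called in C57epi.1.

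Cmpk2 went from 3.89 to 3.84 in C57epi.1 and from 5.07 to 10.42 in Bm12.4, a difference of −5.4 (SE 0.378, adjusted p = 1.12e-08). Psmb9 (−4.09), Ly6e (−3.54), Parp12 (−3.09) and H2-Q4 (−2.8) followed, and Xdh (3.35, adjusted p = 2.18e-06), Apela (3.26), Car6 (3.17, adjusted p = 0.045), Cxcl11 (2.9) and Phf11d (2.75) lay on the other side. Nos2 differed by 2.41, Cxcl9 by 2.33, Irf1 by 1.13, Tap1 by −1.13 and H2-Ab1 by −1.79 (adjusted p = 0.0446). Leaving out 1 array ended the call of H2-Ab1 for 14 of 16: C57epi.1 media replicates 1, 3 and 4 (adjusted p = 0.0677, 0.0771 and 0.0736), treated C57epi.1 replicates 1 to 4 (0.0777, 0.0654, 0.0719 and 0.0785), Bm12.4 media replicates 1 to 4 (0.0828, 0.0625, 0.053 and 0.0539) and treated Bm12.4 replicates 2, 3 and 4 (0.0891, 0.0988 and 0.109). For Car6 it did so for 10: C57epi.1 media replicates 1 and 2 (0.0598 and 0.0624), treated C57epi.1 replicates 2, 3 and 4 (0.106, 0.104 and 0.0892), Bm12.4 media replicates 1 and 2 (0.104 and 0.0571) and treated Bm12.4 replicates 2, 3 and 4 (0.0732, 0.0856 and 0.0907). Bm12.4 carries a mutant H2-Ab1 allele, whose effect on the probes was not tested. With the preset correlation, and not with an estimated one (adjusted p = 0.612 and 0.862), a pair of interferon lists had the higher change in C57epi.1. By the same preset test both lists were lower in C57epi.1 in media, as given above, so these changes started from lower levels. GTPase and effector genes had a positive difference for 5 and a negative one for 1 of 19 (effectors Acod1 −2.34 and Slfn1 2.17, adjusted p = 3.41e-05), with medians of 0.315 and 1.15 in sets A and B. For type I interferon genes these were 5 and 2 of 34, or 15 and 2 adjusted over the list alone (Mx2 2.08, adjusted p = 2.2e-07), with medians of 0.395 and 1.22 in sets A and B. Stromal genes had a lower change in C57epi.1 for 6 of 29, or 9 with 1 higher adjusted over the list alone (Pdgfra −2.64, Pdgfrb −1.92, adjusted p = 2.33e-05, medians −0.445 and −0.29 in sets A and B). None of these 3 lists was called with an estimated correlation (adjusted p = 0.612, 0.862 and 0.844, with 1 list at an unadjusted p under 0.05, and 1 list called with fry). Over all alternatives their adjusted p ran from 4.96e-18 to 0.862. In all, 803 genes differed, 397 higher and 406 lower, 314 by at least 2-fold. Without C57epi.1 media replicate 4 the count was 534, and without replicate 2 it was 1263. Without Bm12.4 media replicate 2 the list test called 5 lists, with cell cycle (adjusted p = 0.000189, with medians of −0.085 and −0.775 in sets A and B with no array left out) and sterol synthesis (adjusted p = 0.00703) added.

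**Figure D5:**
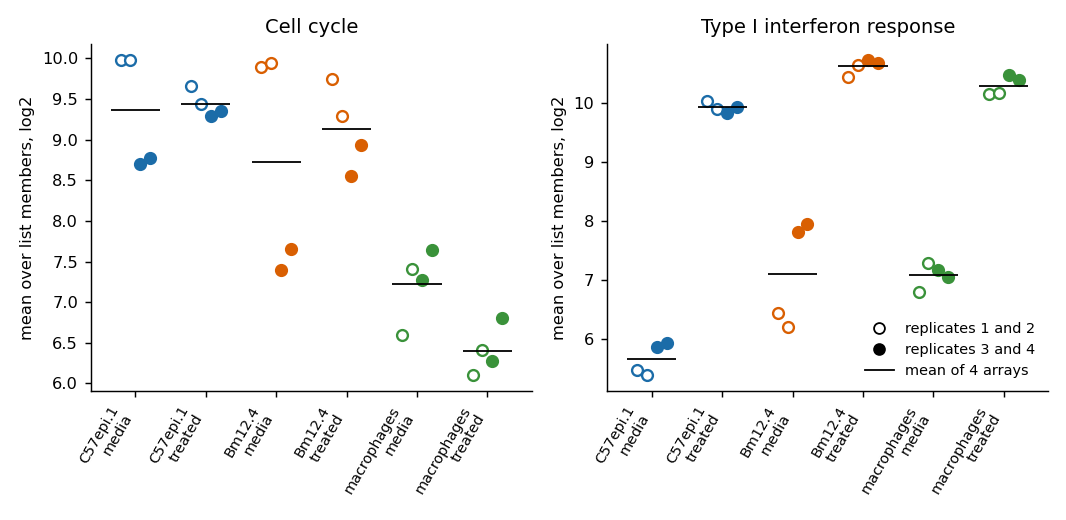
Mean over the measured members of the cell cycle and type I interferon lists on each of the 24 arrays, on the log2 scale, with 1 point per array and a line for the mean of 4. Open points are replicates 1 and 2 and filled points replicates 3 and 4, between which the cell cycle list differs by a median of −2.38 in Bm12.4 media.

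The last question was how lines and macrophages differ within the inflammatory milieu. Treated macrophages held more Cybb, Clec4n, Mmp12, the protease Ctsc and Lyz2, and the lines more Krt19, Nfib, Sparc, Pcolce and Tm4sf1. The treated lines stayed below treated macrophages in MHC class II genes, while the type I interferon genes as a list were not called (adjusted p = 0.73). Costimulatory Cd86 and Pdcd1lg2, which encodes a ligand of the inhibitory receptor PD-1, were far lower in the lines.

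Cybb differed by −10.06 (SE 0.07, adjusted p = 9.73e-30), Clec4n by −10.01, Mmp12 by −9.72, Ctsc by −9.64 and Lyz2 by −9.62. Krt19 differed by 7.8, Nfib by 7.26, Sparc by 6.86, Pcolce by 6.64 and Tm4sf1 by 6.57. The checks of cell type were Ptprc −7.39, Csf1r −7.46, Itgam −8.78, Cd68 −6.46, Vim −0.66, Krt8 1.79, Cdh1 −2.91, Krt18 0.32 (adjusted p = 0.0433) and Epcam −0.08 (adjusted p = 0.474). Krt8 differed through C57epi.1 (9.03), against 5.78 in treated Bm12.4 and 5.62 in treated macrophages. Krt18 was not called without treated C57epi.1 replicate 1 (adjusted p = 0.055), treated Bm12.4 replicate 1, 2 or 3 (0.0708, 0.0708 and 0.0587) or treated macrophage replicate 1, 2 or 3 (0.117, 0.0738 and 0.096). MHC class II genes were lower for 14 of 16 (median −2.64, Ctss −6.83, H2-Ab1 −4.78) and MHC class I genes for 18 of 21 (Cd1d1 −4.67). T cell costimulation genes were lower for 22 and higher for 6 of 33 (Cd86 −7.17, Pdcd1lg2 −6.57), and pattern recognition genes lower for 24 and higher for 3 of 34 (Clec4e −8.16, medians −1.43 and −2.09 in sets A and B). Macrophage markers were lower for 38 of 39 (median −6.52, or −6.37 and −6.63 in sets A and B), alternative activation genes for 16 of 19, dendritic cell markers for 10 of 15 and neutrophil markers for 15 of 20. These 8 lists were also called with an estimated correlation. The other 7 called were not: GTPase genes (8 lower, 1 higher of 19, Slfn1 −6.18, adjusted p = 0.0206, and adjusted p = 0.302 with an estimated correlation), endothelial markers (6 and 1 of 11, Kdr −5.74, adjusted p = 0.0142, and adjusted p = 0.167), sterol synthesis genes (12 higher, 2 lower of 20, Cyp51 2.74, adjusted p = 0.000685, and adjusted p = 0.302), interferon signalling genes (13 lower, 1 higher of 24, Irf8 −6.07, adjusted p = 0.000105, and adjusted p = 0.302 with an estimated correlation), cytokines (20 lower, 9 higher of 40, Il1rn −6.88, medians −0.337 and −0.26 in sets A and B, adjusted p = 0.0128, and adjusted p = 0.144 with an estimated correlation), cell cycle genes (29 higher, 1 lower of 33, Ccna2 5.02, medians 3.38 and 2.52 in sets A and B, adjusted p = 7.62e-09, and adjusted p = 0.302 with an estimated correlation) and stromal genes (20 higher, 5 lower of 29, adjusted p = 1.23e-06, and adjusted p = 0.144 with an estimated correlation). Over all alternatives the adjusted p of these 7 lists ran from 2.25e-15 to 0.302. Type I interferon genes were higher for 7 and lower for 6 of 34 (median −0.01, or 0.0188 and −0.015 in sets A and B, adjusted p = 0.73), with Cmpk2 at −3.14, Parp12 at −3.12 and Mx2 at 2.29. The low values of Cmpk2 and Parp12 came from C57epi.1 (3.84 and 3.86), since treated Bm12.4 (10.42 and 11.25) lay above treated macrophages (10.26 and 10.67). In all, 9711 genes differed, 4853 higher and 4858 lower, 4168 by at least 2-fold.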

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

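The tests of a shared batch and of exchanged arrays, those of the missing rises in C57epi.1, and every comparison within replicates 1 and 2 or 3 and 4 were chosen only after the result was seen.

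The response to the supernatant differed between both lines (their mean) and macrophages for antigen presentation genes, by the interaction term in limma. The MHC class II genes H2-Aa (difference of log2 changes 4.94), Cd74 (4.28) and H2-Ab1 (3.47), the protease Ctss (2.68) and the regulator Ciita (1.73) changed more in the lines. So did Mpeg1 (6.16), Ms4a4d (4.79), Apol10b (4.76), Trim30a (4.58), Cd274 (3.08), Mx2 (2.49), Usp18 (2.31), Il6 (1.9), Cxcl10 (1.69) and Ido1 (1.55). Macrophages changed more in Ms4a4c (−5.71), Ms4a6b (−5.42), Ms4a6c (−5.31), Edn1 (−4.82), Slfn1 (−4.04), Cd40 (−3.37), Cd86 (−2.75), Tnfsf15 (−2.53), Nos2 (−1.9), Tnf (−1.82) and Irf1 (−0.89). For Nos2 and Irf1 this came mainly from Bm12.4. Nos2 rose by 2.5 there, 4.91 in C57epi.1 and 5.6 in macrophages, and Irf1 by 2.41, 3.55 and 3.87. Cmpk2 (−2.17) differed through C57epi.1 (−0.06), since it rose by 5.35 in Bm12.4 and 4.81 in macrophages. Of cell cycle genes, Ccna2 (2.79), Top2a (2.26), Kif11 (2.21) and Nusap1 (2.04) differed, and of sterol genes Fdps (0.75), Fdft1 (0.68), Sc5d (0.65) and Pmvk (−0.69). Leaving out 1 array ended the calls of Ccna2, Top2a and Fdps as given with their values above, and that of Kif11 for C57epi.1 media replicates 3 and 4 (adjusted p = 0.0516 and 0.0506), treated Bm12.4 replicate 1 (0.0504), macrophage media replicates 2, 3 and 4 (0.0676, 0.0752 and 0.093) and treated macrophage replicates 1, 2 and 3 (0.0937, 0.0625 and 0.0523). The lists that differed had medians of 0.939 (type I interferon), 0.338 (MHC class II), −0.107 (T cell costimulation), 0.493 (sterol synthesis) and 0.996 (cell cycle). None of the 5 was called with an estimated correlation (adjusted p = 0.641 for each). High levels of MHC class II genes in macrophages in media leave less room on the array for a rise, and this was not tested.

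The lines differed from each other, by the same test, in interferon and stromal genes. C57epi.1 had the higher change in Xdh (3.35), Apela (3.26), Car6 (3.17), Cxcl11 (2.9), Phf11d (2.75), Nos2 (2.41), Cxcl9 (2.33), Slfn1 (2.17), Slfn2 (2.17), Mx2 (2.08) and Irf1 (1.13). It had the lower change in Cmpk2 (−5.4), Psmb9 (−4.09), Ly6e (−3.54), Parp12 (−3.09), H2-Q4 (−2.8), Acod1 (−2.34), H2-Ab1 (−1.79) and Tap1 (−1.13), and in the stromal genes Pdgfra (−2.64), Pdgfrb (−1.92), S100a4 (−1.83) and Snai1 (−1.49). The calls of Car6 and H2-Ab1 ended without single arrays, as given above. The lists that differed had medians of 0.612 (interferon-inducible GTPases), 0.852 (type I interferon) and −0.255 (stromal genes). None of the 3 was called with an estimated correlation (adjusted p = 0.612, 0.862 and 0.844). Both interferon lists were lower in C57epi.1 in media with the preset correlation, so their higher changes started from lower levels.

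Single arrays stood apart from the other 3 of their group, by the gap to the nearest as a share of the group's range (Dixon's 95% critical value), in 9 of 246 sets tested (3.66%), where chance gives about 1 in 20. In C57epi.1 media these were Cd80 (0.868, level 4.21 against a mean of 4.9) and Cd86 (0.932, 3.57 against 3.15) in replicate 2, and Icam1 in replicate 4 (0.852, 7.95 against 7.69). Ido1 stood apart in treated Bm12.4 replicate 1 (0.958, 4.99 against 4.06) and Il6 in macrophages in media, replicate 2 (0.85, 3.12 against 2.74). List means did so for interferon signalling in macrophages in media, replicate 1 (0.878, 8.59 against 8.69), MHC class I in treated Bm12.4 replicate 1 (0.904, 9.47 against 9.71), MHC class II in treated C57epi.1 replicate 1 (0.843, 7.41 against 7.65) and sterol synthesis in treated Bm12.4 replicate 3 (0.906, 8.14 against 8.33).

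Probe sets outside the comparisons also changed. Of 1621 with several symbols, 70 changed at least 2-fold in C57epi.1, 47 in Bm12.4 and 50 in macrophages. Of 5443 with no symbol, 119, 39 and 110 did.

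Other splits of the arrays into groups of the same sizes were counted for each comparison. In C57epi.1, 1 of 35 splits, the real one, called as many as 3832 genes (highest other 194), and in macrophages 1 of 35 called 2482 (highest other 11). For both this is the smallest share that 35 splits can give, and it is under 0.05. It concerns the assignment of these arrays alone. The labels do not show separate cultures, so chance between cultures was not tested. In Bm12.4, 3 of 35 splits called as many as the real 1445, so by that share chance cannot be excluded. The highest, 3789, set replicates 1 and 2 against 3 and 4 whatever the treatment, which points to a structure of the samples. With a replicate block, 1650 genes were called. Media and treated arrays of Bm12.4 with equal numbers correlated at 0.23 to 0.68, but the equal number was the best match for 2 of 4, so the arrays went together by set more than by number. Of the splits that part all 4 pairs, the other 7 called 0 genes with limma (270 to 1552 at an unadjusted p under 0.05, against 3533 for the real split). So few splits cannot give a share under 0.05, so they do not exclude chance. For C57epi.1 against Bm12.4 in media, 1 of 35 splits called as many as the real 4873, but the split into replicates 1 and 2 against 3 and 4 came to 4826. The replicate block gave 5265, and the other 7 splits that part all pairs called 0 (468 to 3942 at an unadjusted p under 0.05, against 6431). Here too they are too few to exclude chance. The lines against macrophages gave 1 of 100 splits in media (9393, highest other 5546) and 1 of 100 after treatment (9711, highest other 5981). The interaction of lines and macrophages gave 1 of 100 (1611, highest other 746). For these 3, the real assignment called more genes than any other split drawn. Those splits keep neither the sets nor the numbers of the arrays, so chance is not taken as excluded. The interaction between the lines gave 3 of 100 (803, highest other 3423), a share under 0.05. These splits keep neither the sets nor the numbers of the arrays, and the highest other is several times the real count, which again points to a structure of the samples. The share is therefore not taken to exclude chance. The replicate block gave 1162 genes.

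Replicates 1 and 2 stood apart from replicates 3 and 4 in the media arrays of both lines. In replicates 3 and 4, Gins1 was lower by a difference of −2.48 in C57epi.1 and −3.79 in Bm12.4, Rrm2 by −2.04 and −3.83, while Txnip was higher by 3.44 and 2.27 and Irf7 by 1.88 and 3.67. The tables argue against a batch shared by all arrays of a number, since the difference between these sets in macrophages in media correlated across genes with those of the lines at no more than 0.0397, against 0.721 between the lines. They argue against media and treated arrays having been exchanged, since the lowest treated array lay 3.31 above the highest media array in the mean of the interferon-inducible GTPase list. A different growth state of the cultures stays open and is consistent with the values: genes of growth arrest had a median of 0.56 in C57epi.1 and 0.73 in Bm12.4 (15 and 16 of 18 higher in replicates 3 and 4) and genes of replication −1.71 and −2.57 (0 of 17 higher), though the lower cell cycle list had been seen and made this outcome more likely. The split was not confined to media. The difference between the sets in treated arrays correlated with that in media at 0.722 in Bm12.4 and 0.42 in C57epi.1, and the medians in the treated lines were smaller, at 0.21 in C57epi.1 and 0.31 in Bm12.4 for growth arrest and −0.31 and −0.85 for replication. No group of the design gives a biological cause, and a batch of the epithelial cultures was not tested.

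A few genes rose at least 4-fold in Bm12.4 and macrophages but not in C57epi.1. Of 93 genes with such a rise in both, 88 were called up in C57epi.1, 85 of them at least 4-fold, and 4 stood out with a called difference: Cmpk2 (−0.06 against 5.35 in Bm12.4), Psmb9 (0.35 against 4.44), Parp12 (−0.21 against 2.88) and, chosen after its values were seen, 9330175E14Rik (−0.08 against 4.53, difference −4.62). A general lack of response is argued against by the interferon-inducible GTPase list, of which 100% rose in C57epi.1. High levels in media are argued against too, since C57epi.1 lay below Bm12.4 there (median −1.12 over these genes). These genes were picked in part for a rise in macrophages, which came from C57BL/6 mice as C57epi.1 did. Their probes thus gave signal in that strain: in treated macrophages Cmpk2 stood at 10.26, Psmb9 at 11.42, Parp12 at 10.67 and 9330175E14Rik at 6.98. For these genes, this argues against a strain variant under the probes. A variant of the line under the probes, a lost or silenced gene, and a line difference in regulation may each apply, and none was tested.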

How the results depend on the processing

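Replicates 1 and 2 alone, replicates 3 and 4 alone, the set term (1 and 2 against 3 and 4) and the replicate block within the groups compared were chosen only after the data were seen. The other alternatives were planned.

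Of 22879 recomputed values of named genes and lists, 21944 kept their direction and side of the threshold, 606 lost the call, 100 gained one, 227 were called in neither and changed sign, and 2 were called with the opposite sign. These 2 were of the cell cycle list with replicates 1 and 2 alone. In C57epi.1, where the list was not called with all arrays, it stood at −0.42 (adjusted p = 5.53e-05, with 5.71e-06 to 0.996 over all alternatives). In Bm12.4, where it was called up with all arrays, it stood at −0.38 (adjusted p = 6.32e-05, with 4.98e-25 to 0.813). The split of the media arrays shows the cause, since the list was lower in replicates 3 and 4 there. At an adjusted p under 0.01, 63 of 664 named gene calls were lost.

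The 2 comparisons of levels between lines and macrophages kept their gene counts within 1.5-fold of the reported ones under all alternatives, as did eBayes with trend and robust options, aligned medians, quantile normalization, every probe set, the mean of probe sets and the replicate block for all 8 comparisons. The filter on dim genes kept 12286 genes and removed 7652, and moved no gene count by that much. Elsewhere the cause was not tested unless the alternative itself shows it.

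The stricter threshold called fewer genes by construction: 2468 in C57epi.1, 890 in Bm12.4, 1622 in macrophages, 930 for the interaction of lines and macrophages, and 318 (190 at 2-fold) for that between the lines. With the arrays of the groups compared alone, which changes both the degrees of freedom and the residual spread, there were 786 in Bm12.4, 3007 between the lines in media and 438 for their interaction.

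With replicates 1 and 2 alone, 2245 genes were called in C57epi.1 and 426 for the interaction between the lines. With replicates 3 and 4 alone, there were 5830 in C57epi.1 (1536 at 2-fold), 3189 in Bm12.4 (678), 3317 for lines and macrophages (986) and 2401 for the interaction between the lines (900). With the set term, there were 2225 in Bm12.4, 2684 for lines and macrophages and 1954 (491 at 2-fold) for the interaction between the lines.

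List calls depended on the correlation assumed. With an estimated one, 7 lists were called for lines and macrophages in media, 8 after treatment, and 0 for the lines in media and for both interactions (0, 1 and 1 at an unadjusted p under 0.05). Fry, which asks another question, gave 11 lists for the lines in media and 1 for their interaction. For the lines in media, the count was 1 with the filter on dim genes, 3 with the set term, 2 with replicates 1 and 2 alone and 8 with the replicate block within the groups compared.

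Leaving out 1 array gave 2923 to 4262 genes in C57epi.1, 1142 to 1448 in Bm12.4, 2008 to 2331 in macrophages, 8801 to 9525 and 9017 to 9748 for lines against macrophages, 4299 to 5042 for the lines in media and 1311 to 1816 for the interaction of lines and macrophages. The interaction between the lines ranged from 534 (without C57epi.1 media replicate 4) to 1263 (without replicate 2), and its lists from 3 to 5 (without Bm12.4 media replicate 2). Lists for the lines in media ranged from 2 (without C57epi.1 media replicate 2 or Bm12.4 media replicate 4) and 3 (without Bm12.4 media replicate 3) to 7 (without C57epi.1 media replicate 3 or Bm12.4 media replicate 1). Calls near the threshold that single alternatives ended include Ido1 in Bm12.4, Cd40 in C57epi.1, Cd80 in macrophages, and H2-Ab1 and Car6 for the interaction between the lines.

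No signal over background per probe set was used here. At low levels, such as those of Epcam in all groups or Cd86 in both lines, a gene that is off cannot be told from a gene that is weakly on, and a small change there was not detectable.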

Other observations

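The test of mesothelial markers was chosen only after some of them were seen.

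Both lines came from the upper reproductive tract, and their levels in media gave a mixed picture of epithelium. Krt19 stood at 11.31 in C57epi.1 and 11.77 in Bm12.4 against 4.32 in macrophages, and Vim at 13.42 and 12.44. Epcam (3.74 and 3.7) lay at its level in macrophages (3.71), and Cdh1 (4.34 and 4.5) below it (6.65). The cavity-lining genes Upk3b (11.23 and 12.12 against 5.38), Msln (8.89 and 8.55 against 4.9), Wt1 (8.85 and 9.27 against 4.92), Gata6 (10.34 and 11.05 against 5.22) and Bnc1 (8.02 and 9.76 against 3.73) were high in both. Lrrn4 (7.42 and 11.47), Nkain4 (6.18 and 12.21) and Igfbp5 (5.1 and 10.94) were far higher in Bm12.4, and Gpm6a (10.48 and 7.78) in C57epi.1. These genes were chosen after their values were seen.

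The hypothesis that the lines hold cells of mesothelial type, the lining of body cavities, was tested with 16 markers. Of these, 10 (62.5%) lay at least 4-fold above macrophages in each line, past the 60% bound set for the test, but values of 6 had led to the list. These were left out only after the share over all 16 was known, and of the other 10, 4 passed in each line (40%, between the 30% and 60% bounds). Values of Krt8, Krt18, Igfbp5 and Nkain4 among those 10 had been seen too, so no share here is a test on unseen genes and none decides. Calb2 (3.62 and 3.52 against 3.56) and Muc16 (3.1 and 2.92 against 2.91) lay at the macrophage level, and many of the markers are shared with tract epithelium or stroma. Cells of mesothelial type, tract epithelium that lost adhesion genes in culture, and a share of stromal cells may each apply and cannot be told apart here, since no reference cells were on these arrays.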
